A study of Mus musculus with 28 samples.

How the data were processed

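Gene expression was measured in 28 samples of mouse mammary cells, sorted by flow cytometry as YFP-positive cells of normal or oncogene-carrying gland or as tumour cells after collagenase and hyaluronidase digestion. Per the labels, female mice received 3 tamoxifen injections of 5 mg from the age of 4 to 5 weeks, total RNA was extracted with a micro column kit, and biotin-labelled RNA was hybridised to Affymetrix arrays with perfect-match-only probe sets. The authors deposited log2 expression values for 45141 probe sets per array. The notes name R 2.14.0 and state neither the background correction nor the normalization between arrays. The deposited log2 values ran from 1.67 to 12.7 with array medians of 4.40 to 4.50, and at one rank the arrays differed by at most 0.558, so they had been brought to near-identical distributions and were used without further scaling.

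The probe annotation lists 29449 probe sets, of which 28898 carry 1 gene symbol, and 28689 of these matched the reference by gene identifier. The 551 probe sets with several symbols and the 15692 without an entry were left out. For each of 17097 genes the probe set with the highest mean over all arrays was kept, a choice that applied to the 7180 genes with more than 1 probe set. Trp53, Krt17, Tagln, Jag2, Prlr, Ly6a, Areg, Bax and Irs2 were not analysed here. A gene was tested if it lay above the 40th percentile of its array, which was 3.89 to 3.99, on at least 2 arrays of the fit. The files name no genome build, so no positions are given.

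Models were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group and empirical Bayes moderation, to the 16 sorted arrays together (8 groups, 13150 genes), the 12 tumour arrays together (3 groups, 13244 genes) or all 28 arrays (11 groups, 13663 genes) where tumours were compared with normal cells. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. In the contrasts of tumours with normal cells the reference was the mean of the 8-week and 10-month YFP groups. Comparisons were basal against luminal YFP cells at each time, PIK against YFP luminal cells at 8 weeks and basal cells at 10 months, basal against luminal K8-PIK cells, K8-PIK basal against YFP basal cells, luminal against basal K5-PIK cells, K5-PIK luminal against YFP luminal cells, older against younger YFP cells of each gate, K5-PIK and p53-deleted tumours each against K8-PIK tumours, and tumours against the normal cells of their origin. Interactions tested whether the lineage contrast differed by genotype at each time or by age, and whether the oncogene effect differed between luminal cells at 8 weeks and basal cells at 10 months. The genotype contrast includes a different Cre driver for the basal gate at 8 weeks and for the luminal gate at 10 months. Samples were grouped by the labels alone. The labels give no batch or scan date.

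Gene lists were fixed before the data were examined, as were the groups, comparisons, tests, the rule for named genes and the alternative settings, except where stated. There were 25 lists with 362 genes, 323 of them on the array. They cover basal and myoepithelial, luminal, hormone-sensing luminal, luminal progenitor, milk, developmental regulator, proliferation, FOXO-induced, sterol and fatty acid synthesis, glycolysis, ERK feedback, Notch, Wnt, mesenchymal transition, squamous, p53 target, interferon, hypoxia and dissociation-response genes, and markers of immune, endothelial, fibroblast, pericyte, adipocyte and erythroid cells. Lists were tested with limma's rotation test fry, two-sided and adjusted over the lists of a comparison. The camera test was run beside it with a preset correlation of 0.01 and with an estimated correlation. Member counts are given over all genes tested and adjusted over the list alone.

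Normal lineage sets were the genes called and at least 2-fold different between YFP basal and luminal cells. The 10-month set was applied to 8-week comparisons and to tumours, and the 8-week set to 10-month comparisons. Per array, the mean over a set was scaled to 0 and 1 between the YFP group means of the time that defined the set. Scores of K5-PIK and K8-PIK tumours were compared by an exact permutation test, two-sided, over 120 arrangements. Groups of 2 arrays were given as values, since an exact test of 2 against 2 cannot reach the threshold.

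Named genes were chosen per comparison by rule. Of the genes called with replicates of both groups not overlapping, the 10 largest rises and 10 largest falls qualified, or 3 of each for age. For interactions the 3 largest of each among the called genes qualified, without the condition on overlap. Up to 4 called members of each list with the largest change qualified too, and Pik3ca, Krt5, Krt14, Krt8, Krt18, Trp63, Acta2, Esr1, Pgr, Elf5 and Kit did in every comparison. Foxa1 in the contrast of K8-PIK gates, and Tns3, Porcn and Ly6g6e among shared genes, were named after their values were seen.

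Alternative settings were a fit on other arrays (all 28 arrays in place of the sorted or tumour arrays, or only the compared groups where the fit used all), no dim filter, a stricter filter at the 50th percentile, the mean of all probe sets of a gene, quantile normalization, a trended robust prior, replicate number as a block, each compared array left out in turn, the other set tests, a 4-fold limit for the lineage sets and the set of the other time for tumours. Where leaving out an array left 1 array in a group, that array was assumed to vary like the other groups. The mean of the endothelial list, and for basal cells at 10 months that of the dissociation-response list, entered as covariates chosen after seeing the data. The models were tested on simulated data built from these designs: changes of 1 log2 unit were recovered in 20.9% to 70.1% of cases and changes of 2 in 77.3% to 95.5%, with 2.25% to 11.1% of calls false. Comparisons of at least 3 arrays per side were repeated on other splits of the same arrays, at most 100, with seed 11. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.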

Results

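RNA was measured on 28 Affymetrix arrays of cells sorted from the mouse mammary gland, each reporting 45141 probe sets. Mice carried an inducible Cre recombinase, K8CREERT2 in luminal cells or K5CREERT2 in basal cells, and the fluorescent reporter RosaYFP. In some of them Cre also switched on PIK3CA-H1047R, a mutant of the PI3-kinase catalytic subunit that is active without growth factor. Tamoxifen was given at puberty, and YFP-positive cells were sorted 8 weeks or 10 months later through a luminal or a basal gate. Normal cells, called YFP here, came from K8CREERT2 mice for the luminal gate and K5CREERT2 mice for the basal gate, with 2 arrays per gate at each time. Oncogene cells, called PIK, were K8-targeted luminal and basal cells at 8 weeks and K5-targeted luminal and basal cells at 10 months, again 2 arrays each. Tumour cells came from K5-targeted PIK mice (3 arrays), K8-targeted PIK mice (7 arrays) and K8-targeted PIK mice whose p53 alleles were also deleted (2 arrays). The labels do not say that replicates are separate animals, so each p-value measures the spread between these samples, and the small number of arrays limits the precision. Array medians lay between 4.40 and 4.50 on the log2 scale, and replicates of the sorted cells correlated across genes at 0.973 to 0.994. Changes are log2 differences ± SE with limma's adjusted p. The rotation test made 86 gene list calls in 450 tests. Camera with an estimated correlation between genes also called 1 of them, the interferon list in ageing luminal cells. Camera's adjusted p is given beside the calls as the p with an estimated correlation. The rotation test asks whether a list's genes move one way and does not compare them with other genes. Camera makes that comparison, and with the preset correlation it kept 65 of the 86 calls. With the correlation estimated from the data most calls were lost. A high p there means that the list was not shown to move more than other genes, given that correlation. The rotation test asks another question, so its call stands for that question alone.

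Normal basal and luminal cells were compared first, as the reference for every later change of identity. At 8 weeks YFP basal cells had more mRNA of the basal keratins Krt5 (3.69 ± 0.32, adjusted p = 1.12e-05) and Krt14 (3.23 ± 0.31, adjusted p = 2.52e-05) and of Trp63, the transcription factor of basal epithelium (3.85 ± 0.31, 2 against 2 arrays). The contractile genes Acta2 (3.45 ± 0.48), Myh11 (4.04 ± 0.56) and Mylk (4.17 ± 0.45) rose with them. So did Lgr5, a receptor that strengthens Wnt signalling (5.16 ± 0.28), and the secreted Wnt inhibitor Wif1 (5.50 ± 0.31). Luminal cells had more of the oestrogen-receptor partner Foxa1 (-3.78 ± 0.39), the progesterone receptor Pgr (-2.57 ± 0.64), the oestrogen receptor Esr1 (-1.90 ± 0.33), the alveolar transcription factor Elf5 (-2.54 ± 0.28) and the receptor tyrosine kinase Kit (-1.84 ± 0.30). Krt8 (-0.50 ± 0.17, adjusted p = 0.0446) and Krt18 (-0.90 ± 0.27, adjusted p = 0.0253), the luminal keratins, fell less. The identifiers of these genes in the annotation are 110308 for Krt5, 16664 for Krt14, 22061 for Trp63, 11475 for Acta2, 13982 for Esr1, 13711 for Elf5, 16691 for Krt8 and 16668 for Krt18. Across the basal list 16 of 17 measured members rose, and 16 also did so adjusted over the list alone (rotation adjusted p = 3.75e-05, and 0.127 with an estimated correlation). Of 16 luminal list members 8 fell, 14 adjusted over the list alone (adjusted p = 0.0132, and 0.466 with an estimated correlation). Of 9 hormone-sensing genes 7 fell (adjusted p = 0.00148, and 0.318 with an estimated correlation). Proliferation genes were lower in basal cells, with 11 of 23 fallen, among them Mki67 (-1.70 ± 0.57) and Mcm2 (-1.92 ± 0.31), and 12 adjusted over the list alone (adjusted p = 0.0484, and 0.539 with an estimated correlation). Among Wnt pathway genes 7 of 12 rose, including Wnt10a (2.49 ± 0.63) and Dkk3 (3.00 ± 0.39), 9 adjusted over the list alone (adjusted p = 0.00666, and 0.318 with an estimated correlation). Endothelial markers went with the basal gate: 9 of 12 were higher, 11 adjusted over the list alone, with Pecam1 at 2.24 ± 0.62 (adjusted p = 0.0346, and 0.430 with an estimated correlation). The list mean was 4.93 and 5.79 on the luminal arrays against 6.36 and 7.23 on the basal ones. In all, 1373 genes were higher and 2614 lower in basal cells of 13150 tested. The number called was 2094 without YFP luminal replicate 1 and 2367 without YFP basal replicate 1. It was 2319 in the fit of all arrays and 1290 with the endothelial mean as a covariate, chosen after seeing the data.

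The same contrast was drawn in older mice, at 10 months. Krt5 (4.36 ± 0.32, adjusted p = 1.38e-06), Krt14 (4.50 ± 0.31, adjusted p = 1.1e-06), Trp63 (4.63 ± 0.31) and Acta2 (4.32 ± 0.48) were higher in basal cells, and all 17 measured basal list members rose (adjusted p = 7.02e-06, and 0.174 with an estimated correlation). Of 16 luminal list members 13 fell, such as Krt7 (-3.83 ± 0.44) and Cldn3 (-3.30 ± 0.50), and Foxa1 was at -4.30 ± 0.39. In addition 11 of 14 milk genes fell, such as Btn1a1 of the milk fat globule (-4.38 ± 0.53) and the whey protein gene Lalba (-3.68 ± 0.36). The adjusted p was 0.000793 for both lists, and with an estimated correlation 0.379 for the luminal and 0.372 for the milk list. Of 13 mesenchymal genes 9 rose, including Fn1 (2.16 ± 0.50) and Cdh2 (1.78 ± 0.24), with adjusted p = 0.00213, and 0.372 with an estimated correlation. Of 12 endothelial genes 9 were higher in the basal gate (adjusted p = 0.0626). So were 3 of 15 immune genes, such as Cd74 (1.96 ± 0.51, list adjusted p = 0.166), and 1 of 4 adipocyte genes, Fabp4 (2.01 ± 0.69, list adjusted p = 0.599). The count was 2320 higher and 3393 lower. It was 3539 in total without YFP basal replicate 1, 3622 without YFP luminal replicate 2, and 3271 with the endothelial mean as a covariate.

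Lineage by age, tested as the difference between these contrasts, called 7 of 13150 genes. Brinp3 widened in favour of basal cells (2.83 ± 0.41, adjusted p = 0.0307), while the growth factor Igf2 (-3.26 ± 0.48, adjusted p = 0.0363) and Hepacam2 (-2.21 ± 0.27, adjusted p = 0.0268) widened in favour of luminal cells. The change of the gap was 0.67 ± 0.45 for Krt5 (adjusted p = 0.567) and 1.27 ± 0.44 for Krt14 (adjusted p = 0.27). By limma 0 were called in the fit of all arrays (844 at an unadjusted p under 0.05) and 16 with a trended robust prior. Without single arrays the count was 0 for 8-week basal replicate 2, 10-month basal replicate 1 and either 10-month luminal replicate, 3 for either 8-week luminal replicate and 4 for 8-week basal replicate 1.

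**Figure D1:**
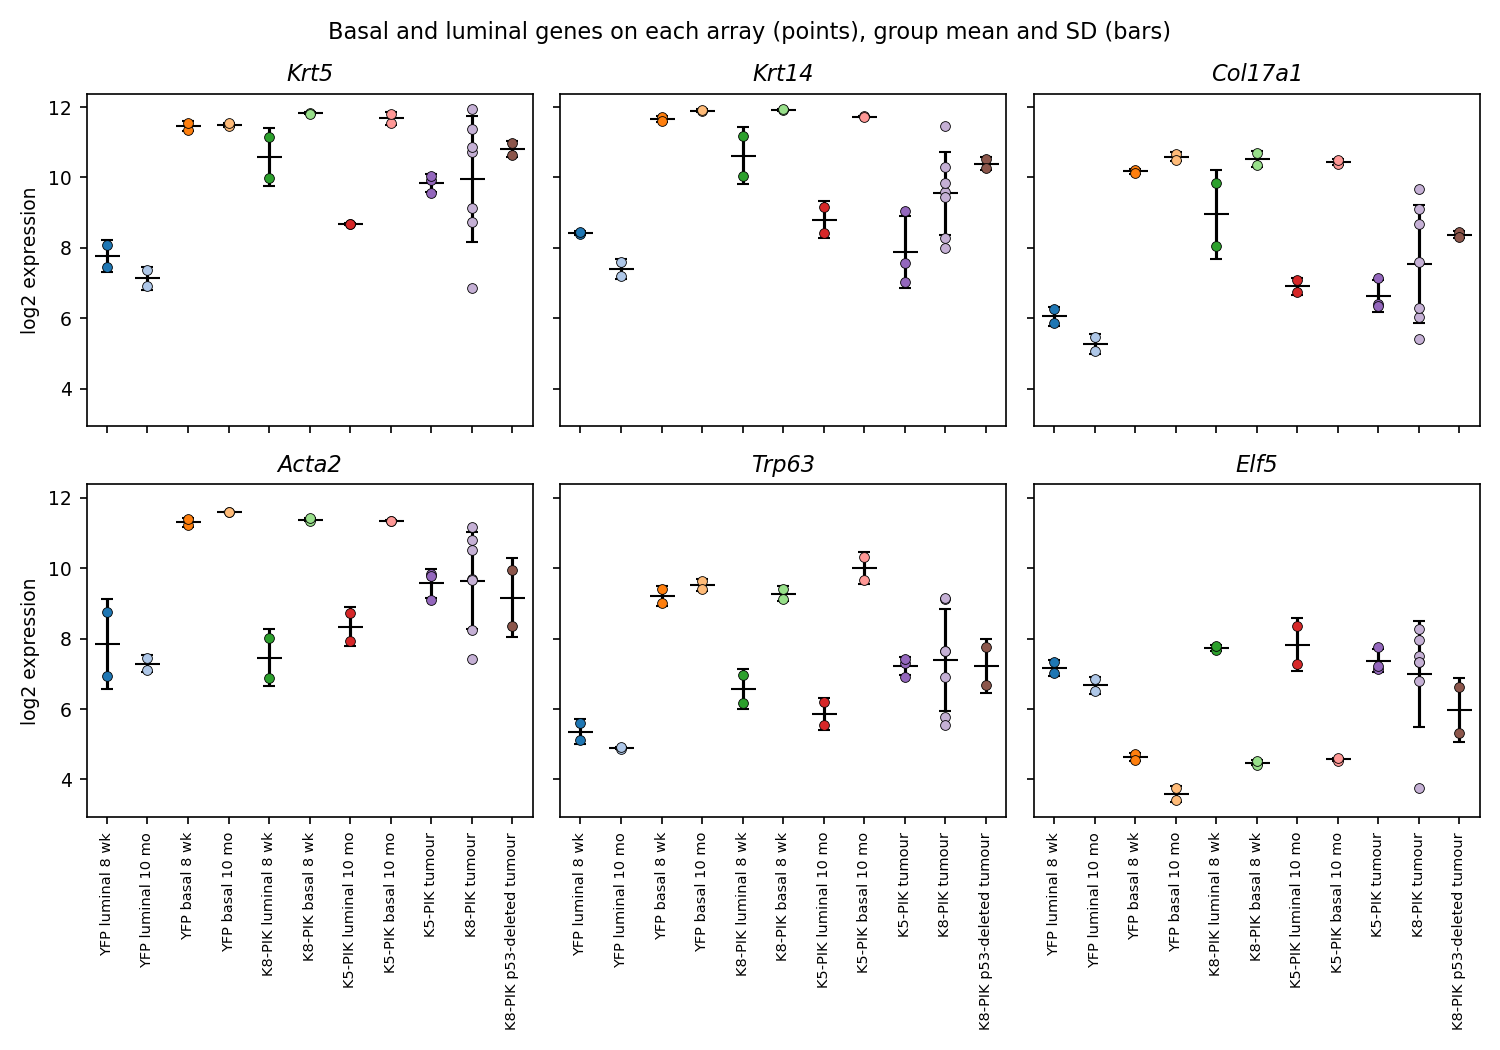
Log2 expression (vertical axis) of Krt5, Krt14, Col17a1, Acta2, Trp63 and Elf5 in each of the 11 groups (horizontal axis), with each array as a point and the group mean and SD as bars. In K8-PIK luminal cells at 8 weeks Krt5 averaged 10.57 against 7.77 in YFP luminal cells, while Acta2 averaged 7.45 against 7.85.

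The effect of the oncogene on luminal cells was read 8 weeks after its induction in K8-targeted cells. Krt5 rose by 2.81 ± 0.32 (adjusted p = 0.00299, 2 against 2 arrays) and Krt14 by 2.19 ± 0.31 (adjusted p = 0.0101). Col17a1 (2.90 ± 0.41, adjusted p = 0.0101) and Lama3 (2.26 ± 0.39, adjusted p = 0.0335), which anchor basal epithelium to its basement membrane, rose with them. The basal transcription factor Trp63 was at 1.20 ± 0.31 (adjusted p = 0.143) and the contractile gene Acta2 at -0.39 ± 0.48 (adjusted p = 0.828). The largest rise was in Amtn, first known from tooth enamel (3.55 ± 0.47, adjusted p = 0.00691). Other genes that rose were the cytokine Il24 (2.84 ± 0.30, adjusted p = 0.0017), the activin subunit Inhba (2.18 ± 0.40), the protease Klk6 (1.85 ± 0.24) and the lipid droplet coat gene Plin2 (1.33 ± 0.21). Genes that fell included Plac8 (-2.54 ± 0.26, adjusted p = 0.0017), the neurotrophin Bdnf (-2.59 ± 0.33), the immunoglobulin-like receptor Pira1 (-3.06 ± 0.31) and Greb1, an oestrogen-induced gene (-2.12 ± 0.36, adjusted p = 0.0309). Keratins of the luminal layer stayed within their error, Krt8 at 0.07 ± 0.17 and Krt18 at 0.04 ± 0.27. Of 17 basal genes 4 rose, 0 fell and 13 did not pass, with 8 risen adjusted over the list alone (rotation adjusted p = 0.0783). Of 9 hormone-sensing genes 1 fell, 5 adjusted over the list alone, with Esr1 at -0.94 ± 0.33 (adjusted p = 0.291) and Pgr at -1.65 ± 0.64 (adjusted p = 0.348). Over the whole set 19 genes were higher and 27 lower, with 1441 at an unadjusted p under 0.05. The count was 6 without YFP luminal replicate 2, 28 without YFP luminal replicate 1, and 10 without PIK luminal replicate 1. Without PIK luminal replicate 2 the balance turned, with 45 higher and 13 lower. The count was 4 in the fit of all arrays, of which 3 were among the 46 of the main fit. The calls named next were therefore not all kept there. Il24, Krt5, Pira1 and Plac8 kept their call without each single array. Krt14 reached adjusted p = 0.0578, 0.0941 and 0.0516 without YFP luminal replicates 1 and 2 and PIK luminal replicate 1.

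K8-targeted cells that sorted through the basal gate at 8 weeks, that is cells of luminal origin by their Cre driver, were compared with the K8-targeted cells of the luminal gate. They had more of the contractile genes Acta2 (3.93 ± 0.48, adjusted p = 0.000149), Myh11 (4.27 ± 0.56), Mylk (4.29 ± 0.45) and Cnn1 (4.12 ± 0.36), and of Trp63 (2.72 ± 0.31, adjusted p = 9.88e-05). Krt5 (1.25 ± 0.32, adjusted p = 0.0148) and Krt14 (1.31 ± 0.31, adjusted p = 0.0107) rose less. The growth factor Ereg, a ligand of the EGF receptor, rose most (5.27 ± 0.62, adjusted p = 0.000113), with Wif1 (4.97 ± 0.31) and the extracellular matrix gene Reln (4.54 ± 0.25). Luminal genes fell: Elf5 by -3.26 ± 0.28 (adjusted p = 1.46e-05), Krt18 by -1.63 ± 0.27, Kit by -1.48 ± 0.30, and the milk genes Lalba (-3.58 ± 0.36) and Csn2 (-3.13 ± 0.99). Foxa1 was at 0.54 ± 0.39 (adjusted p = 0.376). Of 17 basal genes 16 rose (adjusted p = 0.000195, and 0.147 with an estimated correlation). Of 16 luminal genes 12 fell and 1 rose (adjusted p = 0.00459, and 0.335 with an estimated correlation). Of 14 milk genes 10 fell (adjusted p = 0.0024, and 0.291 with an estimated correlation). The luminal progenitor list fell with 4 of 10 members (adjusted p = 7.34e-05, and 0.147 with an estimated correlation). Genes of the ERK feedback list, which the MAP kinase pathway induces, rose with 5 of 12 members such as Etv5 (1.91 ± 0.26) and Dusp6 (1.67 ± 0.23). The list had adjusted p = 0.0039, and 0.291 with an estimated correlation. Endothelial list means were 5.80 and 5.78 in the basal gate and 5.61 and 5.00 in the luminal gate. There were 1170 higher and 1388 lower genes. In total 1147 were called without PIK basal replicate 1, 1162 without PIK luminal replicate 2, and 1232 in the fit of all arrays.

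Set against normal basal cells of the same age, the K8-derived basal cells had Krt5 (0.37 ± 0.32, adjusted p = 0.643), Krt14 (0.27 ± 0.31), Trp63 (0.07 ± 0.31) and Acta2 (0.08 ± 0.48) short of the threshold, and 0 of 17 basal genes passed limma's test over all genes. The luminal factor Foxa1 was higher by 3.72 ± 0.39 (adjusted p = 0.00522, 2 against 2 arrays), at 7.97 against 4.25 in normal basal cells and 8.02 in normal luminal cells. Other genes that rose were the alarmin cytokine Il33 (4.12 ± 0.67, adjusted p = 0.0325), Ereg (3.61 ± 0.62), Inhba (2.52 ± 0.40), the keratin Krt6a (2.94 ± 0.56), Igfbp2 (2.31 ± 0.31) and the fibronectin receptor subunit Itga5 (1.47 ± 0.22). Lgr5 fell by 1.93 (SE 0.28, adjusted p = 0.0174), and Adamts5 (-1.21 ± 0.17) and Medag (-1.16 ± 0.17) fell too. Pericyte markers were lower as a list, with 0 of 5 passing over all genes and 4 fallen adjusted over the list alone (adjusted p = 0.0431, and 0.218 with an estimated correlation). Endothelial list means were 5.80 and 5.78 against 6.36 and 7.23. The change in the lineage gap between PIK and YFP cells at 8 weeks called 1 gene, Foxa1 (4.32 ± 0.55, adjusted p = 0.0447), with Krt5 at -2.44 ± 0.45 (adjusted p = 0.107). The basal cells compared in that gap differ in Cre driver as well as in the oncogene. Altogether 44 genes were higher and 11 lower, against 1834 at an unadjusted p under 0.05. The count was 0 without PIK basal replicate 2, where Foxa1 had adjusted p = 0.0706, 7 without YFP basal replicate 2, and 12 without PIK basal replicate 1. It was 3 in the fit of all arrays and 5 with the endothelial covariate. In the interaction Foxa1 lost its call in the fit of all arrays, where 1 other gene was called, without a dim filter (adjusted p = 0.0941) and with the mean of probe sets (adjusted p = 0.0535). It also lost it without each array except YFP basal replicate 2, where 2 genes were called, and PIK luminal replicate 2, with 10. Without YFP luminal replicate 1 the call passed to 4 other genes.

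The reverse passage was read in K5-targeted PIK mice at 10 months, where cells of basal origin by their Cre driver sorted through the luminal gate. Against K5-targeted PIK cells of the basal gate at the same time they had more Elf5 (3.26 ± 0.28, adjusted p = 6.7e-06, 2 against 2 arrays), Foxa1 (4.02 ± 0.39, adjusted p = 1.55e-05), Kit (3.08 ± 0.30, adjusted p = 1.55e-05) and Prom1 (3.84 ± 0.50). Krt5 (-3.00 ± 0.32, adjusted p = 2.79e-05), Krt14 (-2.93 ± 0.31), Trp63 (-4.13 ± 0.31) and Acta2 (-3.01 ± 0.48) fell, as did Lgr5 (-4.57 ± 0.28) and Wif1 (-4.78 ± 0.31). Esr1 was at 0.76 ± 0.33 (adjusted p = 0.124) and Pgr at 0.77 ± 0.64 (adjusted p = 0.441). Milk genes were higher, with 10 of 14 risen, such as Csn1s1 (3.83 ± 0.74) and Lalba (3.43 ± 0.36), and 12 of 16 luminal genes rose. Both lists had 0.287 as adjusted p with an estimated correlation, and by rotation the adjusted p was 0.00159 for milk and 0.00148 for luminal genes. The tryptophan-degrading enzyme Ido1 rose by 4.70 ± 0.67 and Amtn by 4.37 ± 0.47. Of 17 basal genes 16 fell and of 10 luminal progenitor genes 5 rose, each with adjusted p = 2.34e-05, and 0.0955 with an estimated correlation. Wnt (7 of 12) and ERK feedback genes (6 of 12, with Spry1 at -2.63 ± 0.21) fell, with adjusted p = 0.00239 and 0.00137, and 0.305 for each with an estimated correlation. Hypoxia genes fell with 5 of 11 members (adjusted p = 0.0196, and 0.430 with an estimated correlation), and genes known to respond to tissue dissociation fell with 4 of 11 (adjusted p = 0.0208, and 0.514 with an estimated correlation). The count of 1362 higher and 1735 lower genes became 1764 in total in the fit of all arrays.

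Compared with normal luminal cells at 10 months, which differ from the K5-derived luminal cells in the Cre driver as well as in the oncogene, 0 of 16 luminal list genes passed limma's test over all genes, and 0 adjusted over the list alone. Amtn rose most (5.01 ± 0.47, adjusted p = 0.000285, 2 against 2 arrays), with the cytokine Il17b (3.39 ± 0.51, adjusted p = 0.0036), the matrix protein Fbn2 (2.89 ± 0.17, adjusted p = 5.24e-06), the lipid carrier Apod (2.89 ± 0.54) and the neural crest and mammary progenitor factor Sox10 (1.74 ± 0.26, adjusted p = 0.00333). Some basal genes were higher, Krt5 (1.54 ± 0.32, adjusted p = 0.0162), Krt14 (1.40 ± 0.31, adjusted p = 0.0212) and Myh11 (2.56 ± 0.56) among 5 of 17, while Trp63 was at 0.97 ± 0.31 (adjusted p = 0.0818) and Acta2 at 1.06 ± 0.48 (adjusted p = 0.214). Genes that fell included the EGF receptor ligand Epgn (-4.74 ± 0.58, adjusted p = 0.00121), Plac8 (-3.97 ± 0.26, adjusted p = 1.05e-05), Krt6a (-3.81 ± 0.56), Igf2 (-3.54 ± 0.34), the serotonin-synthesis enzyme Tph1 (-3.48 ± 0.37) and Tbx3, a factor of hormone-sensing luminal cells (-1.68 ± 0.21). Luminal progenitor genes rose with 3 of 10 members, including Kit (1.65 ± 0.30) and Elf5 (1.15 ± 0.28), with adjusted p = 0.00158, and 0.0811 with an estimated correlation. Targets of p53 fell with 2 of 20 members, 8 adjusted over the list alone (adjusted p = 0.00459, and 0.173 with an estimated correlation). The 3 erythroid markers were higher as a list, with Hba-a1 at 1.55 ± 0.31 (adjusted p = 0.0161, and 0.173 with an estimated correlation). Of 841 called genes 273 were higher. The count fell to 119 without YFP luminal replicate 2, 146 without YFP luminal replicate 1 and 412 without PIK luminal replicate 1, rose to 1338 without PIK luminal replicate 2, and was 100 in the fit of all arrays. Amtn, Il17b, Fbn2, Epgn, Plac8, Igf2, Tph1, Krt6a, Tbx3 and Sox10 kept their call without each single array.

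Across these 10-month groups the basal-minus-luminal gap of PIK cells differed from that of YFP cells in 682 genes upward and 258 downward. The luminal cells compared in that gap differ in Cre driver as well as in the oncogene. Epgn (5.10 ± 0.82, adjusted p = 0.00844), Plac8 (4.18 ± 0.37, adjusted p = 0.000675), Krt6a (4.03 ± 0.80) and the matrix proteoglycan Dcn (3.94 ± 0.73) shifted towards the basal gate. Amtn (-4.47 ± 0.66, adjusted p = 0.00629), Sh2d5 (-4.74 ± 0.93) and Sox10 (-1.82 ± 0.36) shifted towards the luminal gate. The gap of Krt5 changed by -1.35 ± 0.45 (adjusted p = 0.0784) and that of Krt14 by -1.57 ± 0.44 (adjusted p = 0.0506). Normal luminal genes defined at 8 weeks shifted upward with 167 of 1252 members and downward with 4 (adjusted p = 0.0424, 0.329 with an estimated correlation, and 0.0936 with a set of at least 4-fold). The count was 153 and 65 without YFP luminal replicates 1 and 2, 85 without YFP basal replicate 1, 255 and 2359 without PIK luminal replicates 1 and 2, and 208 without PIK basal replicate 2. It was 169 in the fit of all arrays, and Plac8 and Amtn kept their call without each array.

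The oncogene's effect on basal cells was read in K5-targeted mice at 10 months, basal gate against basal gate. Krt5 (0.19 ± 0.32, adjusted p = 0.719), Krt14 (-0.17 ± 0.31), Trp63 (0.47 ± 0.31) and Acta2 (-0.25 ± 0.48) did not pass. The branched-chain amino acid enzyme Bcat1 fell by 3.82 (SE 0.33, adjusted p = 0.000227, 2 against 2 arrays), with Ereg (-3.42 ± 0.62, adjusted p = 0.00572), the cytokine Il6 (-2.74 ± 0.34, adjusted p = 0.0015) and Itga5 (-1.73 ± 0.22). The transcription factor Snai2, a member of the basal list, fell too (-1.05 ± 0.16, adjusted p = 0.00277). Rises included the receptor Ephb6 (2.57 ± 0.33, adjusted p = 0.00172), Gpa33 (2.29 ± 0.21, adjusted p = 0.000227), Elf5 (0.98 ± 0.28, adjusted p = 0.0318) and the milk genes Csn3 (1.49 ± 0.39) and Lalba (1.22 ± 0.36). Milk genes rose in 5 of 14 cases (rotation adjusted p = 0.142). Of 17 genes that FOXO factors induce when PI3-kinase signalling is low, 4 rose, among them Txnip (1.58 ± 0.41), Gadd45a (1.40 ± 0.24) and Foxo3 (0.99 ± 0.20), and 0 fell (adjusted p = 0.142). Dissociation-response genes rose with 7 of 11 members, such as Jun (0.98 ± 0.19) and Atf3 (0.95 ± 0.22), 9 adjusted over the list alone (adjusted p = 0.0671). Their list means were 10.6 and 10.9 against 9.83 and 10.0 on the YFP arrays. Endothelial markers were lower, with 6 of 12 fallen, 8 adjusted over the list alone, as Pecam1 (-2.09 ± 0.62) and Cdh5 (-2.49 ± 0.72), and list means of 5.50 and 4.60 against 6.07 and 6.97 (adjusted p = 0.14). In total 1089 genes were higher and 1054 lower. The number called was 343 without YFP basal replicate 1 (110 higher and 233 lower), 1124 without YFP basal replicate 2 (674 and 450), 367 without PIK basal replicate 2 (168 and 199) and 1045 in the fit of all arrays (495 and 550). With covariates chosen after seeing the data it was 472 with the endothelial mean and 0 with the dissociation-response mean by limma, where 1563 had an unadjusted p under 0.05. Both means differ between the compared groups, so the loss of calls does not tell the oncogene from what moves with these lists. Bcat1, Il6, Ephb6, Gpa33, Snai2, Itga5 and Gadd45a kept their call without each single array.

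Oncogene effects in luminal cells at 8 weeks and basal cells at 10 months differed, by the test of the difference, in 633 genes upward and 821 downward, with target cell, time and Cre driver all different. Krt5 (2.62 ± 0.45, adjusted p = 0.0101), Krt14 (2.36 ± 0.44, adjusted p = 0.0132), Col17a1 (3.04 ± 0.58) and Lama3 (2.88 ± 0.55) were raised more in luminal cells. Bcat1 (3.64 ± 0.46, adjusted p = 0.00532) and the coagulation receptor Procr (3.22 ± 0.82) also differed in that direction, while Txnip (-2.81 ± 0.59), Gadd45a (-1.41 ± 0.35), Jun (-1.34 ± 0.27) and Esr1 (-1.59 ± 0.47, adjusted p = 0.0472) differed the other way. FOXO-induced genes differed with 5 of 17 members, all downward (adjusted p = 0.141). The count was 793 and 167 without YFP luminal replicates 1 and 2, 200 and 693 without YFP basal replicates 1 and 2, 455 and 625 without PIK luminal replicates 1 and 2, and 215 without PIK basal replicate 2. It was 359 in the fit of all arrays, and Krt5, Krt14, Bcat1, Sh2d5, Mpp7 and Aen kept their call without each array.

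Ageing was read in YFP cells at 10 months against 8 weeks. In luminal cells Igf2 rose (2.46 ± 0.34, adjusted p = 0.016, 2 against 2 arrays), with Hepacam2 (1.83 ± 0.19, adjusted p = 0.00474) and Cntn1 (1.57 ± 0.19). Sox10 (-1.90 ± 0.26, adjusted p = 0.0134), the xenobiotic and steroid enzyme Cyp1b1 (-2.31 ± 0.28, adjusted p = 0.00601) and Mex3a (-1.63 ± 0.20) fell. Interferon response genes were lower as a list (median change -0.58, rotation adjusted p = 0.00328, and adjusted p = 0.0414 with an estimated correlation), though 0 of 10 passed limma's test over all genes, where 1227 had an unadjusted p under 0.05, and 5 fell adjusted over the list alone. Proliferation genes had a median change of -1.05 with 13 of 23 fallen adjusted over the list alone and 0 over all genes (adjusted p = 0.223). The count was 4 higher and 4 lower, 0 without either 10-month luminal replicate, 2 in the fit of all arrays, 27 with a trended robust prior and 17 with the endothelial covariate.

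In basal cells Brinp3 (3.08 ± 0.29, adjusted p = 0.00139, 2 against 2 arrays), the adhesion receptor Vcam1 (2.19 ± 0.30, adjusted p = 0.00853), Adam12 (2.23 ± 0.39) and Snai2 (0.91 ± 0.16) rose with age. Genes that fell included Prom1 of the hormone-sensing list (-2.35 ± 0.50, adjusted p = 0.0431), the milk genes Lalba (-2.44 ± 0.36, adjusted p = 0.0161) and Btn1a1 (-2.53 ± 0.53), Notch3 (-1.69 ± 0.32) and the luminal gene Elf3 (-1.47 ± 0.27). Of 14 milk genes 3 fell, 11 adjusted over the list alone (adjusted p = 0.028, and 0.401 with an estimated correlation). Of 16 luminal genes 2 fell, 12 adjusted over the list alone (adjusted p = 0.034, and 0.403 with an estimated correlation). The luminal list mean was 9.06 and 9.36 on the 8-week arrays against 7.86 and 8.48 on the 10-month ones. Whether the basal sorts of the 2 times held the same share of luminal cells was not tested. Krt5 (0.04 ± 0.32) and Krt14 (0.25 ± 0.31) did not pass. There were 115 higher and 52 lower genes, and by quantile normalization 51.8% of the called genes were higher rather than 68.9%. The count was 1 without 10-month basal replicate 1, 5 without 8-week basal replicate 2, 109 without 8-week basal replicate 1 (49 higher and 60 lower) and 47 without 10-month basal replicate 2, while Brinp3 kept its call without each single array. By limma 0 genes were called in the fit of all arrays (1629 at an unadjusted p under 0.05).

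Every array was placed between normal luminal and normal basal cells with gene sets from YFP cells of the other time, so that no array of a sorted group both defined and tested a set. A basal score of 0 is normal luminal and 1 normal basal, and the luminal score runs the other way. K8-derived basal cells scored 0.823 for basal and 0.283 for luminal genes, next to 0.772 and 0.301 in normal basal cells at 8 weeks. K5-derived luminal replicates 1 and 2 scored 0.197 and 0.0489 for basal and 0.386 and 0.700 for luminal genes, against means of -0.00386 and 0.856 in normal luminal cells at 10 months. K8-PIK luminal replicates 1 and 2 scored 0.266 and 0.0852 for basal genes, against 0.0521 and 0.0820 in normal luminal cells at 8 weeks, and their luminal score averaged 0.863 against 1.00. In the K8 switch 777 of 1244 basal-set genes rose and 922 of 1798 luminal-set genes fell, with 0.00586 and 0.0552 as adjusted p with an estimated correlation. The K5 switch had 614 of 829 basal-set genes lower and 530 of 1252 luminal-set genes higher, with adjusted p = 0.0196 and 0.133 with an estimated correlation. K8-derived basal cells had 14 basal-set genes higher and 6 lower than normal basal cells (adjusted p = 0.474), and K5-derived luminal cells had 182 luminal-set genes lower and 19 higher than normal luminal cells (adjusted p = 0.0802).

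**Figure D2:**
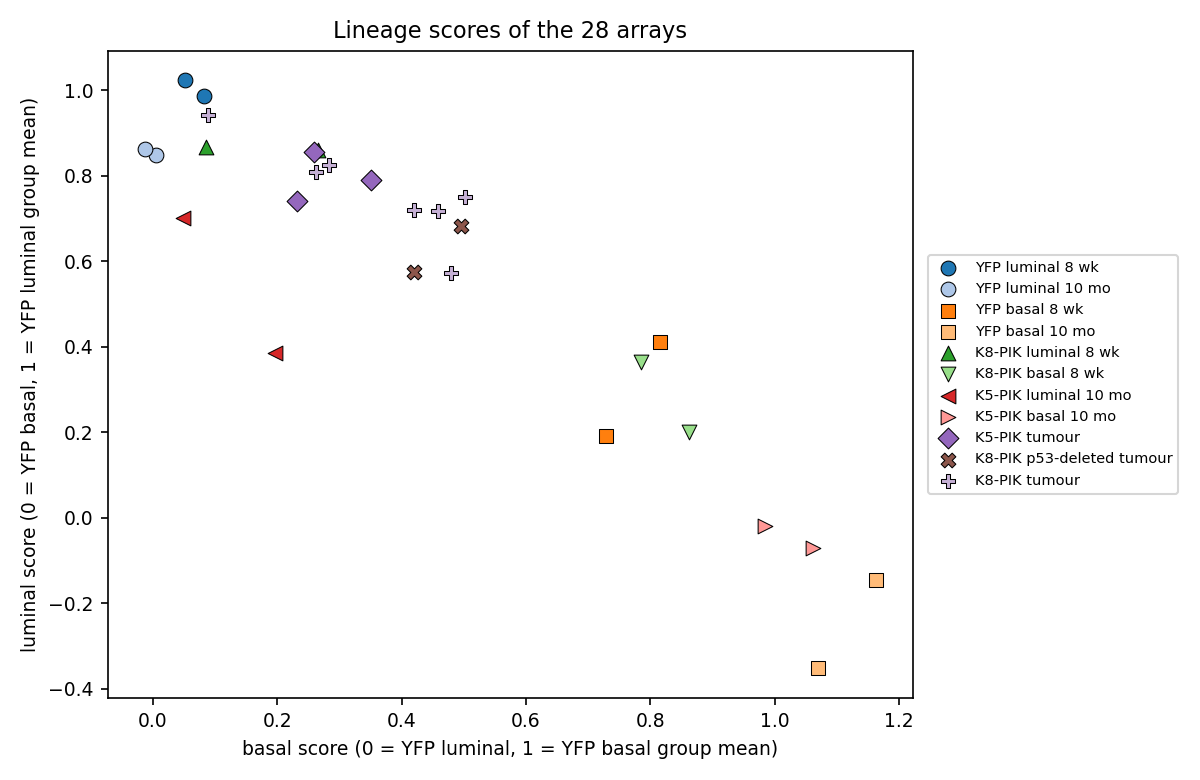
Basal score (horizontal axis) and luminal score (vertical axis) of each of the 28 arrays, without units, where 0 and 1 are the means of the YFP groups that defined the set and each symbol is an array coloured by group. K8-PIK tumours spread from 0.0882 to 0.501 on the basal axis and from 0.572 to 0.941 on the luminal axis.

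Tumours of K5-targeted and K8-targeted PIK mice were compared to ask whether the cell of origin left a mark. The tumours of both origins scored between the normal lineages: 0.281 ± 0.0622 for basal and 0.795 ± 0.0571 for luminal genes in K5-PIK tumours (SD, n = 3), and 0.356 ± 0.151 and 0.762 ± 0.114 in K8-PIK tumours (SD, n = 7). The differences, -0.0752 for basal (exact permutation p = 0.467, two-sided) and 0.0335 for luminal genes (exact permutation p = 0.608, two-sided), did not pass. The luminal difference was 0.183 with a set of at least 4-fold (exact permutation p = 0.183, two-sided) and 0.0724 by quantile normalization (exact permutation p = 0.3, two-sided), and the basal one -0.0452 by quantile normalization (exact permutation p = 0.667, two-sided). Krt14 was at -1.67 ± 0.66 in K5-PIK relative to K8-PIK tumours (adjusted p = 0.508), Krt5 at -0.10 ± 0.89 (adjusted p = 0.977), Esr1 at 0.76 ± 0.43 (adjusted p = 0.589) and Elf5 at 0.38 ± 0.78 (adjusted p = 0.881). By limma 0 of 13244 genes passed, with 1225 at an unadjusted p under 0.05, and 0 of the 25 lists passed, the basal list at adjusted p = 0.929 (median -0.06, mean 0.01, tested direction down) and the Notch list at 0.625. In simulated data of this design 7.46% of changes of 0.5 log2 units, 46.3% of changes of 1 and 77.3% of changes of 2 were recovered. The count was 1 without K8-PIK tumour replicate 2. It was 150 with replicate number as a block, though the numbers were not taken to pair the arrays. With that block the normal basal set was lower in K5-PIK tumours (rotation adjusted p = 0.00325, and 0.0189 with an estimated correlation).

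Deletion of p53 together with the oncogene was read in K8-targeted tumours. Cdkn2a, which encodes the cell-cycle inhibitors p16 and ARF, rose by 3.36 ± 0.16 (adjusted p = 1.24e-06, 2 against 7 arrays), from 4.53 to 7.89. Ereg (4.97 ± 0.39, adjusted p = 0.000123), the growth cone protein gene Gap43 (3.43 ± 0.18, adjusted p = 2.56e-06), the neurotrophic factor Gdnf (2.49 ± 0.28, adjusted p = 0.00401) and mesothelin, Msln (2.44 ± 0.28, adjusted p = 0.00451), rose too. So did the drug transporter Abcb1a (2.42 ± 0.37). Genes that fell included the non-classical MHC gene H2-T23 (-1.68 ± 0.25, adjusted p = 0.0244), the small GTPase gene Rhoj (-1.87 ± 0.27), the AKT phosphatase Phlpp1 (-1.40 ± 0.25, adjusted p = 0.0493) and the basement membrane collagen Col4a6 (-1.66 ± 0.30). Trp53 itself was not analysed here. Of 20 p53 target genes 0 passed by limma over all genes, where 2615 had an unadjusted p under 0.05, and 0 adjusted over the list alone (median change -0.05, adjusted p = 0.626). Mesenchymal genes had a median change of 2.04, with 4 of 14 risen adjusted over the list alone and 0 over all genes (adjusted p = 0.383), beside a fibroblast list median of 1.54 (adjusted p = 0.394). Squamous genes had a median of 0.26 (adjusted p = 0.394) and immune markers 0.01 (adjusted p = 0.842). Altogether 30 genes were higher and 13 lower. Without K8-PIK tumour replicate 3 the count was 1027, without replicates 4, 5, 6 and 7 it was 19, 9, 14 and 8, and without p53-deleted replicate 1 it was 16. Ereg, Gap43, Cdkn2a, Gdnf and Msln kept their call without each array. The count was 1158 in the fit of all arrays, 26 with a stricter dim filter, 25 by quantile normalization and 23 with a trended robust prior. It was 2 with replicate number as a block, so most of the genes just named lost their call there. The numbers were not taken to pair the arrays.

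K8-PIK tumours were compared with normal luminal cells of both times, their lineage of origin by Cre driver. The basal genes Krt5 (2.49 ± 0.63, adjusted p = 0.0164), Trp63 (2.27 ± 0.53, adjusted p = 0.0103), Acta2 (2.09 ± 0.55, adjusted p = 0.0209) and Krt14 (1.64 ± 0.48, adjusted p = 0.0327) were higher in tumours, 7 against 4 arrays. Carbonic anhydrase Car12 (3.05 ± 0.28, adjusted p = 4.08e-06), the protease inhibitor Serpina3n (3.80 ± 0.60, adjusted p = 0.000694), the matrix proteoglycan Vcan (3.49 ± 0.52) and fibronectin, Fn1 (3.43 ± 0.77), rose. The hormone receptors Pgr (-2.38 ± 0.56, adjusted p = 0.0108) and Esr1 (-1.35 ± 0.33, adjusted p = 0.0144) fell, with Pira1 (-2.75 ± 0.21, adjusted p = 3.41e-07), Plac8 (-2.85 ± 0.44) and Tph1 (-3.32 ± 0.39). Elf5 was at 0.07 ± 0.55 and Krt8 at -0.48 ± 0.19 (adjusted p = 0.11). Of 17 basal genes 8 rose, 12 adjusted over the list alone (adjusted p = 0.0092). Of 9 hormone-sensing genes 4 fell, 7 adjusted over the list alone (adjusted p = 0.00856). Glycolysis genes rose with 3 of 12 members, such as Hk2 (1.23 ± 0.24), and 9 adjusted over the list alone (adjusted p = 0.0092). Sterol and fatty acid synthesis genes rose with 4 of 15, such as Insig1 (1.89 ± 0.30) and Fasn (0.69 ± 0.13), with adjusted p = 0.0092. Interferon genes rose with 4 of 12, 7 adjusted over the list alone, as Irf7 (1.31 ± 0.27), with adjusted p = 0.0256. Notch genes rose with 3 of 13, as Hey1 (1.28 ± 0.36), with adjusted p = 0.0256. For each of these 6 lists the adjusted p was 0.270 with an estimated correlation. Fibroblast markers went along, with 3 of 10 higher, as Col3a1 (3.15 ± 0.81), and 6 adjusted over the list alone (adjusted p = 0.0427, and 0.304 with an estimated correlation). The count was 611 higher and 837 lower of 13663. It was 457 in total without 8-week luminal replicate 1, 831 without 8-week luminal replicate 2, and 523 and 499 without 10-month luminal replicates 1 and 2. It was 547 in the fit of the compared arrays alone.

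K5-PIK tumours were set against normal basal cells of both times. Lgr5 fell by 5.55 (SE 0.30, adjusted p = 5.71e-10, 3 against 4 arrays), with Krt14 (-3.89 ± 0.58, adjusted p = 9.33e-05), Trp63 (-2.15 ± 0.64, adjusted p = 0.016), Acta2 (-1.88 ± 0.68, adjusted p = 0.0412), Col17a1 (-3.75 ± 0.75) and Snai2 (-2.38 ± 0.22), while Krt5 was at -1.63 ± 0.77 (adjusted p = 0.117). Luminal genes rose, as Elf5 (3.27 ± 0.67, adjusted p = 0.00115), Foxa1 (3.41 ± 0.77, adjusted p = 0.00225), Kit (2.54 ± 0.55), Krt18 (1.20 ± 0.29) and Esr1 (1.41 ± 0.41, adjusted p = 0.0129). The enzymes Ido1 (5.82 ± 1.10, adjusted p = 0.000628) and arginase, Arg1 (4.60 ± 0.74, adjusted p = 0.000162), which break down tryptophan and arginine, were among the largest rises. Of 17 basal genes 11 fell (adjusted p = 0.000742, and 0.436 with an estimated correlation). Of 16 luminal genes 9 rose (adjusted p = 0.0266, and 0.665 with an estimated correlation). Sterol and fatty acid synthesis genes rose with 8 of 15 members, as Dhcr7 (2.34 ± 0.32) and Elovl6 (2.03 ± 0.26), with adjusted p = 0.00024, and 0.399 with an estimated correlation. ERK feedback genes fell with 4 of 12 and rose with 1, as Spred1 (-1.79 ± 0.29), with adjusted p = 0.0266, and 0.665 with an estimated correlation. Pik3ca, the gene of the PI3-kinase catalytic subunit, fell and was at -0.68 ± 0.14 (adjusted p = 0.00105). Endothelial markers were lower with 6 of 12 (adjusted p = 0.014, and 0.665 with an estimated correlation). The count was 2124 higher and 1978 lower, and no alternative moved it by more than 1.5 times, with 3005 to 3729 called without single arrays.

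**Figure D3:**
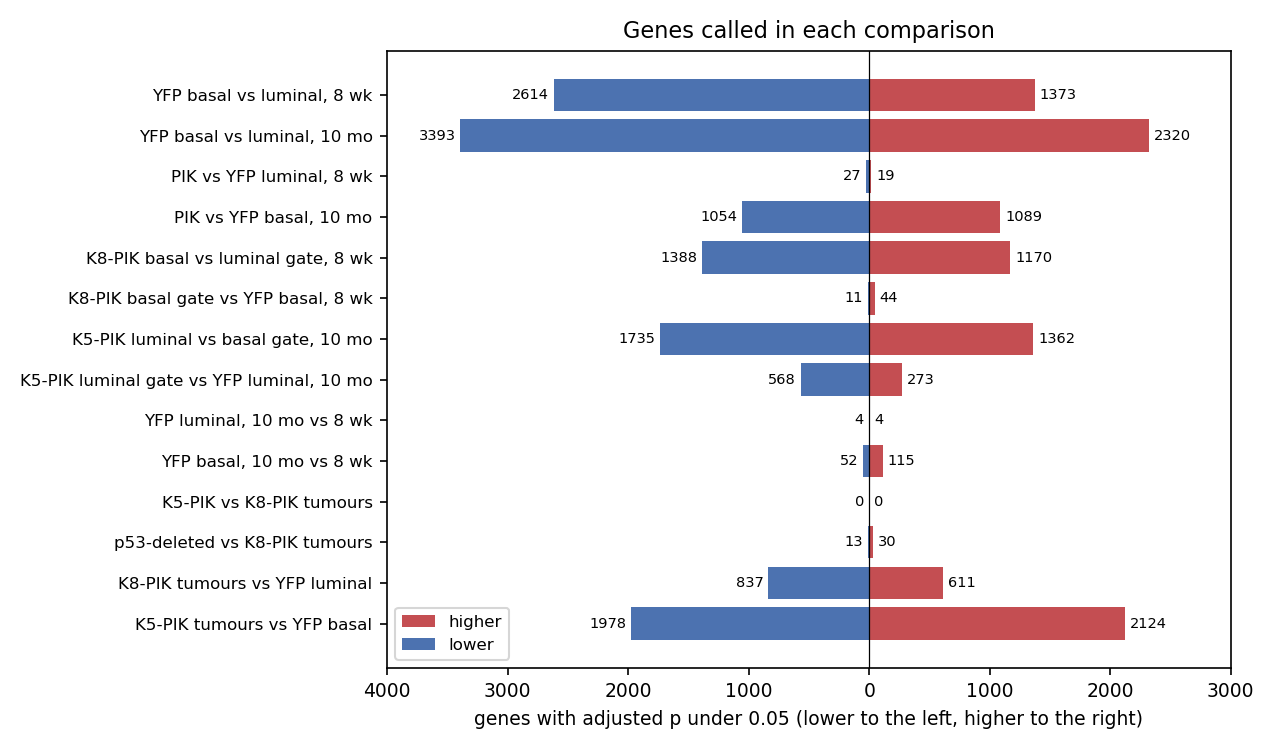
Number of genes with an adjusted p under 0.05 (horizontal axis, higher to the right in red and lower to the left in blue) in each of the 14 pairwise comparisons (vertical axis). The bars run from 0 genes between K5-PIK and K8-PIK tumours to 3393 lower and 2320 higher between normal basal and luminal cells at 10 months.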

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

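The tests of basal cells in the luminal gate, of a lower epithelial share, of a mislabelled tumour and of stromal cells in a tumour sort were chosen after the result was seen, and the tests of endothelial cells and of other splits before.

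Krt5, Krt14, Col17a1 and Lama3 were raised in PIK luminal cells at 8 weeks, 4 of 17 members of a basal list that did not pass (adjusted p = 0.0783), and Krt14, Col17a1 and Lama3 lost their call without single arrays. Acta2, Myh11, Mylk and Cnn1 were not called. A candidate explanation is basal cells passing the luminal gate, which sorting should remove. The raised basal genes would need at least 28.8% of such cells by Lama3, 42.7% by Krt14 and 50.5% by Krt5, and at the smallest of these shares Acta2 would reach 9.80 against the 7.45 measured. The smallest gap among Acta2, Myh11, Mylk and Cnn1 was 2.35 log2 units, which excludes normal basal cells as the whole source. The estimate used the levels of YFP basal cells. K8-derived PIK basal cells, which are YFP-positive under the same Cre driver as the luminal cells, were not tested as a source. With each array left out in turn the smallest share ran from 12.3% (Lama3, without PIK luminal replicate 1) to 49.8%, and the smallest gap from 1.67 to 2.58. A partial gain of basal expression within luminal cells carrying the oncogene may remain, as a hypothesis, along with a change in which luminal cells were sorted, and neither was tested.

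Endothelial markers were lower in PIK than in YFP basal cells at 10 months, with a median of -1.45. Endothelial cells in the YFP basal sort, which sorting for YFP through the basal gate should remove, may account for this: over 12 sorted arrays not compared, the markers moved together between replicates with a mean correlation of 0.577, against a median of 0.00691 and a 95th percentile of 0.137 over 10000 random lists. Fibroblast markers had a median change of 0.121 and immune markers 0.0894, while the upper quartile of endothelial markers was -0.71. These values argue against more cells of all non-epithelial types in the YFP sort. They do not bear on a share of epithelial cells lowered by endothelial cells alone. Pericyte markers had a median of -0.278, with 4 of 5 below 0. Of 1048 other genes that were lower, 18 followed the endothelial mean with a correlation above 0.8, or 1.72%, against 2.37% of all genes tested. With the endothelial mean as a covariate, which itself differs between the groups, 472 genes were called rather than 2143, and 397 were called in both. How much of the contrast beyond the markers goes with these cells stays open. An effect of the oncogene on vessels near the gland stays open and untested.

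K8-PIK tumour replicate 3 stood apart from the other 6 in Krt8 (10.5), Krt18 (9.83), Elf5 (3.76, under the 40th percentile of that array, 3.97), the luminal list mean (7.68) and the luminal progenitor list mean (6.07), by the gap between the farthest sample and its neighbour. Across 38 such measures 6 were picked out, where chance gives about 1 in 20, or 1.9. The measures overlap, since Krt8 and Krt18 are on the luminal list and Elf5 on the luminal progenitor list. They are therefore not separate observations. Without this tumour the p53 contrast called 1027 genes, and on those genes its median position was 0.768 of the way to the p53-deleted tumours, but Cdkn2a, which rose with p53 deletion here, was at 0.059. A mislabelled p53-deleted tumour and a p53-intact tumour that looks alike cannot be told apart, since Trp53 was not analysed here and the 2 tests point opposite ways. Several stromal cell types in the sort, which the purification of tumour cells should remove, could not be settled either, with fibroblast markers at 8.07 against a median of 6.38 in the others and endothelial markers at 4.71 against 5.10, within the others' range.

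The other sample picked out by its gap was K8-PIK tumour replicate 1, with a squamous list mean of 6.25.

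Effects that differed between groups by the test of the difference were as follows. The lineage gap differed between PIK and YFP cells at 8 weeks in 1 gene, Foxa1 (4.32), with the Cre driver of the basal cells different too. At 10 months the Cre driver of the luminal cells differed too, and the gap differed in 940 genes. Among them were Epgn at 5.10, Aoc1 at 4.20, Plac8 at 4.18, Sh2d5 at -4.74, Amtn at -4.47 and Ramp3 at -3.90. The luminal progenitor and squamous lists differed there too, each with rotation adjusted p = 0.027, and adjusted p = 0.299 and 0.445 with an estimated correlation. The oncogene effect differed between luminal cells at 8 weeks and basal cells at 10 months in 1454 genes, with Sh2d5 at 5.07, Mpp7 at 4.23, Bcat1 at 3.64, Pcp4 at -4.33, Pianp at -4.01 and Hdac11 at -3.72. The lineage gap differed by age in 7 genes, including Brinp3 (2.83), the drug transporter Abcb1b (1.87), Cdc27 (1.77), Igf2 (-3.26), Hepacam2 (-2.21) and Cntn1 (-1.95).

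Other splits of the same arrays were counted for the 3 comparisons with at least 3 arrays on each side. Between K5-PIK and K8-PIK tumours the real split called 0 genes. Every split reaches a count of 0, so the 100 of 100 splits that did so decide nothing about chance. The highest other called 604 and set K8-PIK tumour replicates 1, 2 and 3 apart from the rest. Of the other splits 15 called any gene, and their median was 0. That split was picked because its count was the highest, so it does not by itself show a structure of the samples. For K8-PIK tumours against normal luminal cells, with both YFP times as 1 group, the real split called 1492 genes. The highest other called 2081 and set K8-PIK tumour replicates 4, 5 and 7 and the YFP luminal arrays apart from the remaining tumours. As many as the real count were called by 2 of 100 splits, the real one included. Chance is thus unlikely, but a split that mixed tumours with normal cells called more genes than the real one. For K5-PIK tumours against normal basal cells the real split called 3971 and the highest other 3384. Of 35 splits 1, the real one, called as many. That is the smallest share that 35 splits can give, so chance is unlikely but not excluded.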

How the results depend on the processing

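The endothelial and dissociation-response covariates were chosen after seeing the data, and all other alternatives before. The largest shifts in the median change of the tested genes were -0.106 with the dissociation-response covariate for the oncogene in basal cells and -0.0757 by quantile normalization for the lineage by genotype interaction at 8 weeks. Named genes kept their side of the threshold, and where called also their direction, in 933 of 954 cases by quantile normalization. The number was 944 with a trended robust prior, and 945 of 950 with the stricter filter. The direction of genes called in neither setting was not checked. They did so in 901 of 954 without a filter, 908 of 950 with the mean of probe sets, 923 of 954 with the block, 575 in a fit on other arrays and 3983 of 5316 with 1 array left out. Replicates share only a number in the titles. Within each sorted group replicate 2 was subtracted from replicate 1, gene by gene, and these differences were correlated between groups. Over 28 pairs of groups the correlations ran from -0.0775 to 0.386, with 12 above 0.1 and 0 as far below 0. Between tumours of one number from the 2 origins, deviations from the group mean correlated at 0.0933, -0.0917 and 0.211. Among the sorted groups the highest were 0.386 between YFP basal cells of the 2 times and 0.365 between the K5-PIK gates, against 0.0496 between the K8-PIK gates. That all pairs beyond 0.1 were positive points to some structure shared by number. The labels name no shared animal or day, so the arrays were not taken as paired. Whether the 2 K5-PIK gates share animals stays open, and with the block the K5 switch called 3414 genes rather than 3097. Genes above the 40th percentile on fewer than 2 arrays of a fit were not tested. Quantile normalization kept every count within 1.5 times except that of the p53 contrast but moved the share of called genes that were higher from 80% to 65.8% in K8-derived basal against normal basal cells, from 32.5% to 47% in K5-derived luminal against normal luminal cells and from 50.8% to 60.5% for the oncogene in basal cells. Except where fewer arrays or genes were tested, the cause was not tested.

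In a fit on other arrays the number of genes called was 2319 for lineage at 8 weeks, 4 for the oncogene in luminal and 1045 in basal cells, 1232 for the K8 switch, 3 for K8-derived basal cells and 1764 for the K5 switch. It was 100 for K5-derived luminal cells, 2 for age in luminal and 0 in basal cells (limma, 1629 at an unadjusted p under 0.05), 1158 for p53 deletion and 547 for K8-PIK tumours against luminal cells. For interactions it was 169 by genotype at 10 months, 359 by oncogene and 0 for lineage by age (limma, 844 unadjusted).

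With replicate number as a block it was 70 for the oncogene in luminal cells, 112 for K8-derived basal cells, and 23 and 473 for age in luminal and basal cells. It was 150 between tumour origins, 2 for p53 deletion, 2513 for K8-PIK tumours against luminal cells, and 1738, 2221 and 41 for the interactions by genotype at 10 months, by oncogene and by age. A trended robust prior gave 27 for age in luminal cells, 23 for p53 deletion, 2 for the genotype interaction at 8 weeks and 16 for lineage by age. The p53 count was 26 with the stricter filter and 25 by quantile normalization. The genotype interaction at 8 weeks fell to 0 by limma without a filter (1545 unadjusted) and with the mean of probe sets (1205 unadjusted).

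With the endothelial mean as a covariate the counts were 1290 and 3271 for lineage at 8 weeks and 10 months, 472 for the oncogene in basal cells, 5 for K8-derived basal cells and 17 for age in luminal cells. That covariate turned Tie1 to -0.0321 and Cdh5 to -0.17 in lineage at 8 weeks, and Pecam1 to 0.13 and Rgs5 to 0.0194 for the oncogene in basal cells, where removing what goes with the markers is the alternative's own construction. With the dissociation-response mean 0 genes passed by limma for the oncogene in basal cells (1563 unadjusted), and Hdac11 turned to -0.54 and Hey1 to -0.34. That mean itself was 10.6 and 10.9 on the PIK basal arrays against 9.83 and 10.0 on the YFP ones. Adjusting for it also removes part of the group contrast, so the count of 0 does not tell dissociation from oncogene.

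Gene list tests called 135 of 450 with camera's preset correlation and 1 with an estimated one, against 86. Lineage set tests called 20 and 4 of 24, against 9. The block called the luminal set in K5-derived luminal cells (adjusted p = 0.0266, and 0.257 with an estimated correlation) and the basal set between tumour origins, downward (adjusted p = 0.00325, and 0.0189 with an estimated correlation). In addition the normal luminal set between tumour origins turned upward with adjusted p = 0.0232 under the preset correlation and 0.531 under an estimated one, against 0.712 by rotation. By rotation it also turned upward with the block (adjusted p = 0.246) and the 4-fold limit (adjusted p = 0.29), and kept its direction with the set of the other time (adjusted p = 0.766). With the preset correlation these 3 gave 4.48e-05, 1.33e-22 and 0.0424.

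With each array left out in turn the counts ran from 2094 to 3298 for lineage at 8 weeks, 3539 to 4659 at 10 months, 6 to 58 for the oncogene in luminal and 343 to 1952 in basal cells, 1147 to 1942 for the K8 switch, 0 to 46 for K8-derived basal cells, 2316 to 2799 for the K5 switch, and 119 to 1338 for K5-derived luminal cells. They ran from 0 to 8 and 1 to 109 for age in luminal and basal cells, 0 to 1 between tumour origins, and 8 to 1027 for p53 deletion. They ran from 457 to 1786 and 3005 to 3729 for tumours against luminal and basal cells. For the interactions by genotype at 8 weeks and 10 months, by oncogene and by age they ran from 0 to 10, 65 to 2359, 167 to 1522 and 0 to 8. Score differences between tumour origins ran from -0.12 to -0.0509 for basal and 0.00187 to 0.0632 for luminal genes. By limma the counts of 0 had 1185 unadjusted for K8-derived basal cells without PIK basal replicate 2, and 733 and 615 for age in luminal cells without 10-month replicates 1 and 2.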

Other observations

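The tests named here were planned, except the overlap and correlation of the oncogene effects, which were chosen after the data were seen. Developmental regulators of the mammary lineages, a mixed list, separated the gates: at 10 months 7 of 12 were higher and 1 lower in normal basal cells, with the homeobox gene Prrx1 at 4.28 ± 0.35 and Id4 at 3.34 ± 0.34 (adjusted p = 7.69e-05, and 0.372 with an estimated correlation). In K5-PIK tumours against normal basal cells 5 of the 12 fell and 1 rose (adjusted p = 4.09e-05, and 0.399 with an estimated correlation), with Id4 at -1.65 ± 0.45. Adipocyte markers passed as a list in no comparison. In K5-PIK tumours 1 of 4 fell, Fabp4 (-3.69 ± 0.91), and the list had a median of 0.07, a mean of -0.80 and a tested direction of down (adjusted p = 0.535). Sterol and fatty acid synthesis genes were lower in normal basal than luminal cells at 10 months with 6 of 14 fallen, as Fdps (-1.90 ± 0.30) and Dhcr7 (-1.72 ± 0.31), with adjusted p = 0.0031, and 0.561 with an estimated correlation. Squamous genes fell there with 4 of 11, as Sprr1a (-4.33 ± 0.73), with adjusted p = 0.00164, and 0.379 with an estimated correlation.

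Few genes were shared by the oncogene effects in luminal cells at 8 weeks and basal cells at 10 months. Of 19 genes higher in luminal and 1089 higher in basal cells 0 were shared, where 1.57 would be by chance (Fisher's exact p = 0.398). In opposite directions Inhba and Tns3 were higher in luminal and lower in basal cells (1.52 by chance, Fisher's exact p = 0.661), and Porcn and Ly6g6e the reverse (2.24 by chance, Fisher's exact p = 1). Plk2 was lower in both (2.16 by chance, Fisher's exact p = 0.72). Across 13150 genes the changes correlated at -0.238 (Pearson) and -0.269 (Spearman), with no arrays in common, and genes are not independent replicates.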
